A study of Mus musculus with 8 samples.

How the data were processed

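Ribosome-bound RNA was immunopurified from dorsal striatum and nucleus accumbens of Drd1-EGFP/Rpl10a (CP73) mice older than 20 months with antibodies against green fluorescent protein, per the labels' protocols, and 8 libraries were sequenced. Each library was placed in its region by its title, 4 per region. The labels number the replicates 1 to 4 but do not say whether each came from 1 animal or a pool, so p-values measure the spread between these samples. No unpurified input was analysed here, so enrichment over the whole tissue was not measured.

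The deposited values are raw counts of reads per gene symbol, not normalized, as whole numbers for 32531 genes in each library. Reads were aligned to the mm10 mouse genome with STAR 2.0.0e and counted with HTSeq, per the submitters' processing notes. The gene annotation, the strand setting of the counting and the read filters were not given in the sources used here. The tables also held totals of reads with no gene, with more than 1 gene and with more than 1 alignment, which together made up 27.1% to 40.6% of each library's counted reads. These totals were left out of library sizes and tests. Since reads aligned to several places were not assigned to genes, members of families with near-identical copies, such as ribosomal protein genes, Hspa8 and the calmodulin genes, are uncertain in level. Of 105 genes named here with a position in GENCODE M21, a GRCm38 annotation that shares the mm10 coordinates, 34 have an exon that overlaps another gene, 29 of them on the opposite strand. Penk, Reln, Nnat, Gnas, Hpca, Lypd1 and Foxp1 are among these, and their counts could include reads of the neighbour or miss reads shared with it. Coordinates are those of GENCODE M21, 1-based.

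Gene counts per library ran from 7466970 to 12639641, and 14032 to 16223 genes had at least 1 count. A count of 3 corresponds to between 0.237 and 0.402 CPM. The biological coefficient of variation was 0.415 over all tested genes. Medians of its fitted trend with abundance were 0.171 for genes over 100 CPM and 0.773 for genes under 5 CPM. Low-abundance genes thus need larger differences to be called. No pair of libraries agreed within sampling noise in a chi-square comparison of their counts.

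Differences between regions were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalization, filterByExpr with a minimum count of 10), leaving 12467 genes, with region as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are accumbens over dorsal striatum, with standard errors taken from the fold change and its F statistic. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Counts were simulated in a single run from the real means, library sizes and dispersions for this comparison, with 12172 genes tested. In them the test called 9.38% of genes changed 1.5-fold, 45.3% of those changed 2-fold and 73.4% of those changed 4-fold, and 1.11% of its calls were false. The counts were drawn from the model that the test fits, without deviations shared across genes. They therefore do not give the false rate of the real comparison.

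Before the data were examined, 46 gene lists of cell types, regional markers and pathways were fixed, and those with at least 4 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Older gene symbols were matched through a RefSeq synonym table. No gene symbol matched the list of mitochondrially encoded genes, which was therefore not tested. The rule for named genes, also fixed beforehand, took Drd1, Drd2 and Rpl10a, the 15 genes with the largest absolute log2 fold change in each direction among called genes averaging at least 5 CPM with no overlap between regions and with predicted-gene symbols left out, and for each list up to 4 called members with the largest absolute log2 fold change and up to 3 of the highest mean CPM. The text describes the first 2 kinds and part of the third, picked after the values were seen with preference for members whose call held with each library left out. Some genes that the rule took are not reported here. Lars2 and AK140265, and the calcium signalling and copine genes among the closing observations, were chosen after their values were seen.

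Alternatives fixed beforehand were RLE and upper-quartile normalization, no filter on low counts, a stricter filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, the replicate number as a block, a covariate of astrocyte, oligodendrocyte and microglia markers, each library left out in turn, camera with an estimated correlation, and fry. Thinning all libraries to the smallest total, leaving out Rn45s, Lars2 and AK140265, removing each library's trends with GC content and transcript length, and leaving out accumbens 2 and dorsal striatum 3 together were added after seeing the data. Length and GC content were known for 95.7% of tested and 97.8% of called genes.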

Results

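RNA bound to tagged ribosomes was sequenced from 2 regions of the mouse striatum, the dorsal striatum and the nucleus accumbens. The animals carried the transgene Drd1-EGFP/Rpl10a (CP73), for translating ribosome affinity purification, in which cells that use the promoter of the dopamine D1 receptor gene make the ribosomal protein L10a fused to green fluorescent protein. Polysomes were pulled down from dissected tissue with antibodies against the fluorescent protein. This step is meant to enrich translated transcripts of D1 receptor-expressing cells, most of them direct-pathway spiny projection neurons, but enrichment was not measured here. All mice were older than 20 months, and each region had 4 immunopurified libraries. The design asked which transcripts of these cells differ between the 2 regions at that age. The counts assigned to genes ranged from 7466970 to 10363145 per dorsal library and from 10831937 to 12639641 per accumbens library. Every accumbens library was larger than every dorsal one (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow).

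The libraries separated by region along the first principal component of log2 CPM (counts scaled to a common library size), which held 26.5% of the variance and on which no dorsal library reached any accumbens library. Accumbens 2 and dorsal striatum 3 lay at its opposite ends and had the lowest median rank correlations with the other libraries, 0.927 and 0.935. The median Spearman correlation across genes was 0.954 between dorsal libraries, 0.940 between accumbens libraries and 0.934 between regions. The transcript of the 45S ribosomal RNA precursor, Rn45s, took 3.58% ± 1.79 of gene counts in the dorsal libraries (SD, n = 4) and 6.11% ± 0.464 in the accumbens libraries (two-sided exact permutation p = 0.0571). Reads not assigned to a gene made up 31.6% ± 3.05 of all counted reads in dorsal striatum and 37.5% ± 2.22 in accumbens (SD, n = 4 each, two-sided exact permutation p = 0.0286).

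Between accumbens and dorsal striatum, 464 of 12467 tested genes differed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 200 of them higher in accumbens and 264 higher in dorsal striatum. Among the genes with the smallest adjusted p, Dlk1, an imprinted Notch-family ligand (chromosome 12, 109452823 to 109463336), went from 187 ± 25.6 CPM in dorsal striatum to 704 ± 57.7 CPM in accumbens (SD, n = 4 each; log2 fold change 1.91 ± 0.13 SE, adjusted p = 5.54e-07). The cannabinoid receptor gene Cnr1 (chromosome 4, 33924593 to 33948831) stood at 265 ± 52.4 CPM in dorsal striatum and 46.01 ± 9.71 CPM in accumbens (log2 fold change -2.53 ± 0.19 SE, adjusted p = 8.87e-07). Rgs4, a brake on G protein signalling, stood at 1120.2 ± 137 and 356 ± 45.7 CPM (log2 fold change -1.65 ± 0.13 SE, adjusted p = 1.23e-06). Fold changes of at least 2 were found for 240 of the called genes, 139 higher in accumbens and 101 higher in dorsal striatum. The 4 values of each region did not overlap for 1208 of all tested genes, or 9.69%, where chance gives 2.86%. With the level of astrocyte, oligodendrocyte and microglia markers as a covariate, 117 genes were called higher in accumbens and 150 higher in dorsal striatum. DESeq2 called 375 genes higher in accumbens and 369 changed at least 2-fold, and edgeR without a filter on low counts 350 and 371.

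**Figure D1:**
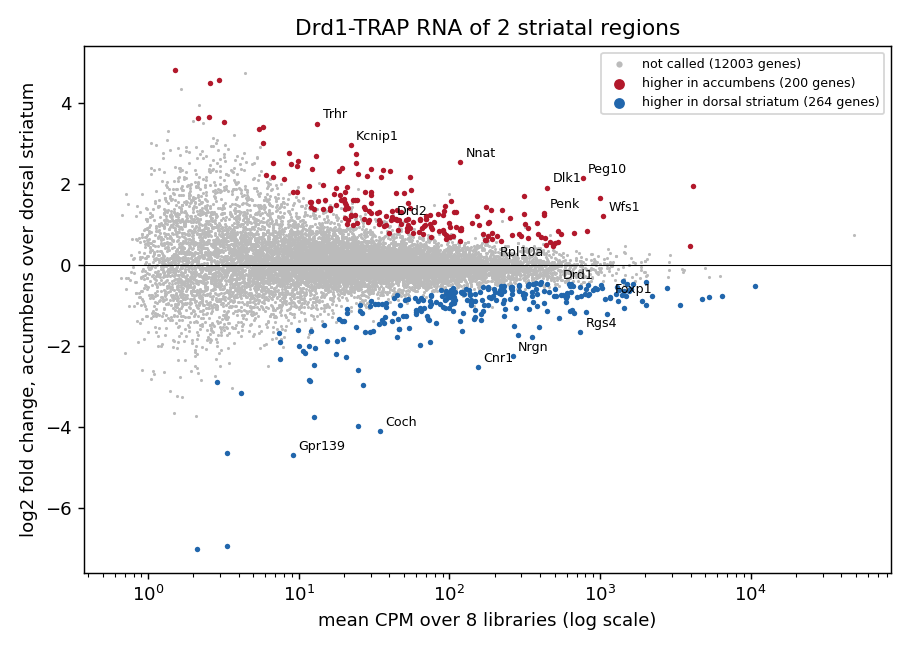
Each point is a tested gene, with its mean CPM over the 8 libraries on a log axis and its log2 fold change, accumbens over dorsal striatum, on the vertical axis. Coloured points are the 200 genes called higher in accumbens and the 264 called higher in dorsal striatum, and the largest differences are among genes of low and middle abundance.

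Among genes that averaged at least 5 CPM and whose regions did not overlap, the 15 with the largest accumbens excess had log2 fold changes from 2.37 (Arhgap36) to 3.49 (Trhr, a receptor for thyrotropin-releasing hormone). They included Kcnip1, a potassium channel-interacting protein at 4.998 ± 2.74 CPM in dorsal striatum and 39.2 ± 9.38 CPM in accumbens (SD, n = 4 each). The axon guidance cue Ntn1, the delta opioid receptor gene Oprd1, the synaptic organizer Cbln4, the imprinted gene Nnat and the neuropeptide gene Cartpt belonged to the same 15. Col12a1, Lcp2, Kirrel, Dlx1, Fat4 and AW551984 did too. In the other direction, the 15 genes ran from -2.13 (Sfrp1, a secreted WNT antagonist) to -4.69 (Gpr139, an orphan receptor at 17.6 ± 3.06 CPM in dorsal striatum and 0.684 ± 1.04 CPM in accumbens). Coch stood at 64.97 ± 11.02 and 3.77 ± 1.72 CPM, and Nrgn, which encodes the calmodulin-binding protein neurogranin, at 435 ± 125 and 91.3 ± 17.1 CPM. Ddit4l, Fam84b, Synpo2, Fam198b, Klhl1, Clspn, Cnr1, Cyp2s1, Cd59a, Pld5 and Sgpp2 made up the rest. Of the 30 genes, 9 lost their call when some single library was left out. Kirrel and Dlx1 lost it without accumbens 3 (adjusted p = 0.0577 and 0.0577), Cd59a without dorsal striatum 1 (0.0762) and Sfrp1 without dorsal striatum 3 or accumbens 3 (up to 0.125). Oprd1 lost it without dorsal striatum 3 or 4 or accumbens 2 (adjusted p up to 0.134) and Cbln4 without dorsal striatum 2 or 4 or accumbens 2 (up to 0.0918). Fat4 lost it without dorsal striatum 3 or 4 or accumbens 3 or 4 (adjusted p up to 0.136) and Col12a1 without dorsal striatum 1 or 3 or accumbens 2 or 3 (up to 0.0835). Lcp2 kept it only without dorsal striatum 2 or accumbens 3 (adjusted p otherwise up to 0.0842). With the glial marker covariate the log2 fold changes were 2.39 for Lcp2, 2.37 for Oprd1, 2.81 for Cbln4, 2.48 for Fat4 and -2.28 for Cd59a, and these genes were not called (adjusted p = 0.130, 0.110, 0.0944, 0.0782 and 0.0778). DESeq2 did not call Cbln4 (adjusted p = 0.0901), and limma-voom did not call Oprd1 (0.0776) and Sfrp1 (0.0568). Single libraries moved some fold changes by more than 1.5 times. Without accumbens 1 the log2 fold change was -6.64 for Gpr139 and -4.59 for Ddit4l, where all libraries gave -3.98. Without accumbens 2 it was 1.86 for Oprd1 (2.76 with all). Without accumbens 4 it was -3.86 for Synpo2 (-2.95 with all) and -2.83 for Sgpp2 (-2.19 with all). Without dorsal striatum 2 it was 4.56 for Col12a1 (3.35 with all) and 3.92 for Lcp2 (3.02 with all). Without dorsal striatum 1 it was 3.38 for Cbln4 (2.70 with all).

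Genes known to mark the regions differed in the direction of their names. All 6 known dorsal striatum genes were called higher in dorsal striatum, 6 adjusted over the list alone, with a median log2 fold change of -1.34 (camera adjusted p = 1.67e-37, and 0.00356 with an estimated correlation). They were Cnr1, Coch, Reln (-1.35), an extracellular matrix protein, Gpr155 (-1.34), the sodium channel subunit gene Scn4b (-1.30) and Id4 (-0.97). Of 14 known accumbens genes, 8 were called higher in accumbens, 13 adjusted over the list alone, and all 14 had positive log2 fold changes (camera adjusted p = 1.37e-36, and 0.0142 with an estimated correlation). The endoplasmic reticulum protein gene Wfs1 rose from 638 ± 56.9 to 1470.5 ± 191 CPM (SD, n = 4 each), the retrotransposon-derived imprinted gene Peg10 from 282 ± 90.9 to 1251 ± 223 CPM, and Hap1, which encodes a huntingtin-binding protein, had a log2 fold change of 1.21 ± 0.14 SE.

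Markers of the striosome and matrix compartments also parted. Of 10 striosome genes, 6 were called higher in accumbens and 0 higher in dorsal striatum, or 7 and 1 adjusted over the list alone (camera adjusted p = 8.94e-09, and 0.0422 with an estimated correlation). Kcnip1, Nnat, Lypd1 (1.20), Sema5b (1.06) and the opioid peptide precursor gene Pdyn (1.02) were among the 6. Of 7 matrix genes, 4 were lower in accumbens and 1 higher, or 5 and 1 adjusted over the list alone, with a median log2 fold change of -0.78 (camera adjusted p = 1.06e-05, and 0.0315 with an estimated correlation). The calcium-binding protein gene Calb1 fell from 209.6 ± 28.1 to 86.3 ± 11.1 CPM (SD, n = 4 each). The log2 fold changes of Rasgrp2, a GTPase regulator, and the cadherin gene Cdh8 were -1.25 ± 0.21 and -0.78 ± 0.15 SE. Id4, the other of the 4, is also on the list of known dorsal striatum genes.

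Imprinted genes were shifted toward accumbens, with 24 of 30 tested members at positive log2 fold changes (camera adjusted p = 1.26e-09, and 0.0315 with an estimated correlation). Of these, 5 were called higher in accumbens and 1 higher in dorsal striatum, or 10 and 3 adjusted over the list alone. Besides Dlk1, Peg10 and Nnat, the stimulatory G protein gene Gnas rose from 185 ± 50.6 to 444 ± 53.3 CPM (SD, n = 4 each). Dlk1, Peg10 and another tested member are also on the list of known accumbens genes, and Nnat is on that of striosome genes. The abundant imprinted transcripts Peg3 and Meg3 were not called, with log2 fold changes of 0.11 ± 0.11 SE for Peg3 (adjusted p = 0.727) and -0.51 ± 0.18 SE for Meg3 (adjusted p = 0.144), though Meg3 was called lower in accumbens without a filter on low counts (0.0345), with the glial marker covariate (0.0249) and without dorsal striatum 4 (0.0463).

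**Figure D2:**
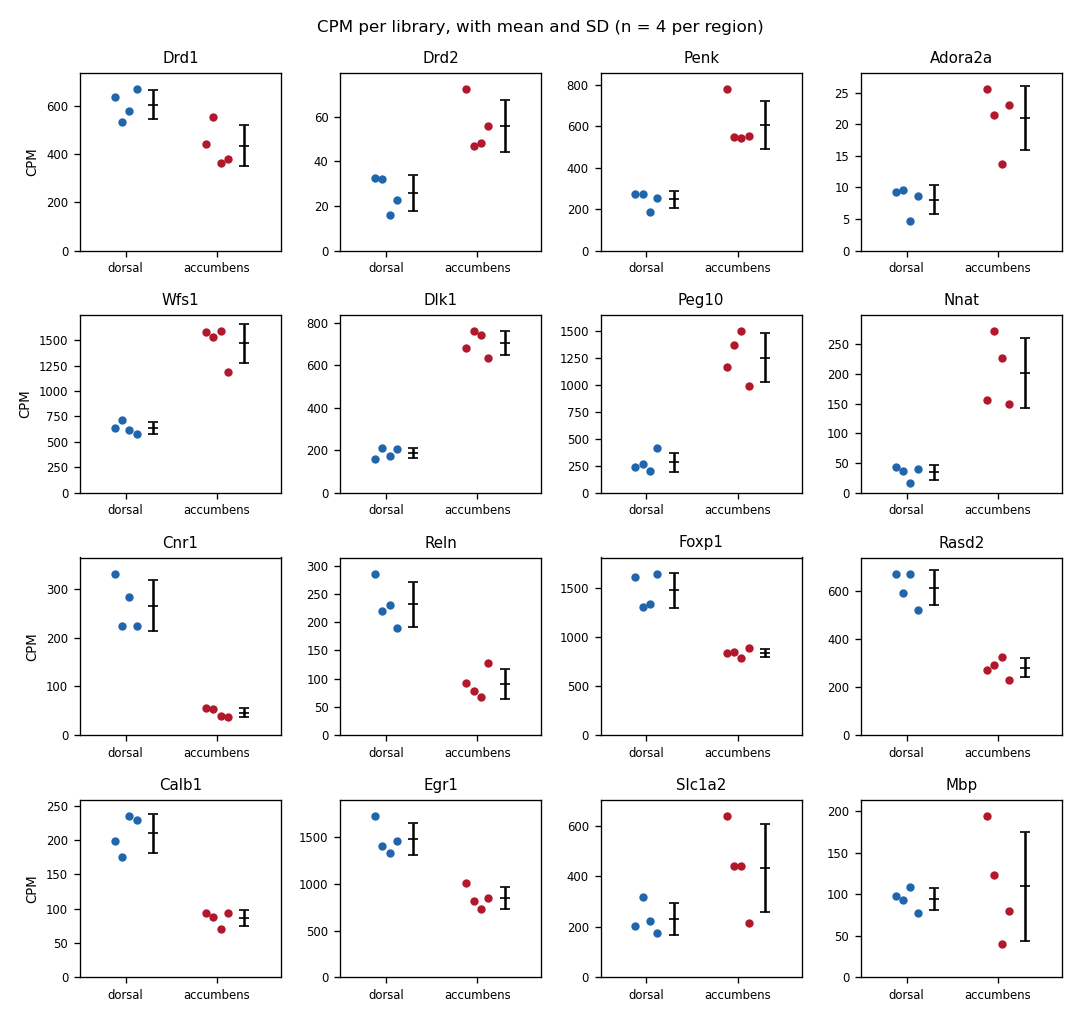
Points are CPM values of single libraries for 16 genes in dorsal striatum and accumbens, each axis starting at 0, with the mean and SD of 4 libraries beside them. Wfs1, Dlk1, Peg10, Nnat and Penk lay higher in every accumbens library, Cnr1, Reln, Foxp1, Rasd2, Calb1 and Egr1 lower, and Slc1a2 and Mbp overlapped between regions.

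Among the projection neuron markers, the gene behind the transgene's promoter, Drd1 (chromosome 13, 54051183 to 54055705), stood at 605 ± 60.9 CPM in dorsal striatum and 435 ± 86.5 CPM in accumbens (SD, n = 4 each) and was not called (log2 fold change -0.47 ± 0.14 SE, adjusted p = 0.0750). It was called lower in accumbens by DESeq2 (adjusted p = 0.0329), by limma-voom (0.0187) and by edgeR without a filter on low counts (0.0398), without accumbens 2 (0.0167) and without both accumbens 2 and dorsal striatum 3 (0.0245). Rpl10a, whose protein carries the tag, was not called either (194 ± 35.3 and 206 ± 25.2 CPM, adjusted p = 0.868). Markers of indirect-pathway neurons, which the D1 promoter should not mark, all had positive log2 fold changes, with a median of 1.11 over 7 genes (camera adjusted p = 2.23e-07, and 0.0917 with an estimated correlation). The enkephalin precursor gene Penk rose from 248 ± 40.9 to 606 ± 115 CPM (SD, n = 4 each) and the adenosine receptor gene Adora2a from 8.04 ± 2.27 to 20.96 ± 5.10 CPM. The D2 receptor gene Drd2, at 25.8 ± 7.97 CPM in dorsal striatum, had a log2 fold change of 1.11 ± 0.25 SE (adjusted p = 0.0167). These 3 were the called members, and 3 were called when adjusted over the list alone. The call of Drd2 was lost without dorsal striatum 3, dorsal striatum 4 or accumbens 1, at adjusted p up to 0.0759. That of Adora2a was lost without any single dorsal library and without accumbens 1 or accumbens 4, at adjusted p up to 0.101. With the glial marker covariate the log2 fold changes were 0.88 for Drd2 (adjusted p = 0.183) and 1.16 for Adora2a (0.266), where the fit without it gave 1.11 and 1.38. The 42 glial, vascular and interneuron markers measured beside them had a median of 0.59. Of 9 direct-pathway markers, Pdyn was higher in accumbens (211 ± 37.9 and 427 ± 37.2 CPM), while the transcription factor genes Ebf1 (-1.25) and Eya1 (-0.55) were higher in dorsal striatum, and 1 and 3 were called when adjusted over the list alone. That list was not called (median log2 fold change -0.36, camera adjusted p = 0.0560), but was with upper-quartile normalization (adjusted p = 0.0488), without a filter on low counts (0.0336), with limma-voom (0.0462) and with fry (0.0427). It was also called without dorsal striatum 2 (adjusted p = 0.0457), dorsal striatum 3 (0.0222) or accumbens 2 (0.0470) and without both of the latter (0.0144). With the glial marker covariate the log2 fold change of Eya1 was -0.50 (adjusted p = 0.0745).

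Markers shared by all striatal projection neurons were shifted toward dorsal striatum, with a median log2 fold change of -0.34 (camera adjusted p = 4.78e-11, and 0.0288 with an estimated correlation). Of 18 tested, 7 were called lower in accumbens and 0 higher, or 11 and 0 adjusted over the list alone. The phosphodiesterase gene Pde10a stood at 2794 ± 171 CPM in dorsal striatum and 1656 ± 242 CPM in accumbens, and the transcription factor gene Foxp1 at 1479 ± 180.1 and 839 ± 43.3 CPM (SD, n = 4 each). Log2 fold changes were -1.13 ± 0.14 SE for the GTPase gene Rasd2, -1.26 ± 0.24 for Actn2, -0.77 ± 0.12 for Rgs9 and -0.71 ± 0.14 for the transcription factor gene Bcl11b. Other abundant members were not called, such as Gnal (-0.30 ± 0.098 SE, adjusted p = 0.117) and Arpp21 (-0.11 ± 0.11 SE, adjusted p = 0.726). Gnal was called by limma-voom (adjusted p = 0.0272). With the glial marker covariate the log2 fold change of Bcl11b was -0.51 (adjusted p = 0.0851). All 9 tested markers of eccentric projection neurons, a minor class, had positive log2 fold changes, 3 of them called and 4 adjusted over the list alone (camera adjusted p = 4.69e-05, and 0.0941 with an estimated correlation). Lypd1 stood at 25.3 ± 4.14 CPM in dorsal striatum and 57.96 ± 10.6 CPM in accumbens (SD, n = 4 each). Of the called members, only Lypd1 kept its call with each library left out in turn. Lypd1 and another called member are also on the list of striosome genes.

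Markers of other cell types lay mostly above 0 on the log2 scale, with few calls. The mean level of astrocyte, oligodendrocyte and microglia markers, as centred log2 CPM, was -0.27 ± 0.57 in dorsal striatum and 0.27 ± 0.39 in accumbens (SD, n = 4 each, two-sided exact permutation p = 0.171). The astrocyte list had a median log2 fold change of 0.67 over 9 genes (camera adjusted p = 0.0460, and 0.364 with an estimated correlation). Its 1 called member, the glutamate transporter gene Slc1a2, stood at 229.9 ± 62.3 CPM in dorsal striatum and 433 ± 173 CPM in accumbens (SD, n = 4 each), and 2 members passed adjusted over the list alone. Both the list and Slc1a2 lost their calls without dorsal striatum 1, 3 or 4 or accumbens 1, 2 or 3, at adjusted p up to 0.320 for the list and 0.166 for Slc1a2. The list was not called with limma-voom (adjusted p = 0.0857) or fry (0.130). Slc1a2 was not called by DESeq2 (adjusted p = 0.0927), by limma-voom (0.0753), with upper-quartile normalization (0.0513) or with GC and length trends removed (0.0513). GABA interneuron markers, such as Sst (0.50 ± 0.27 SE, adjusted p = 0.414), had a median of 0.50 over 5 genes, 1 of them called when adjusted over the list alone (camera adjusted p = 0.0460, and 0.222 with an estimated correlation). Of these, edgeR called 0, 1 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. That list's call was lost without dorsal striatum 1, 3 or 4 or accumbens 1 or 3, at adjusted p up to 0.0886, and also with the glial marker covariate (median 0.53, adjusted p = 0.162), thinned libraries (0.125), GC and length trends removed (0.0610) and fry (0.0657). Neuroblast and dividing cell markers had a median of 0.88 over 7 genes, of which 1, Dlx1, was called and 4 passed adjusted over the list alone (camera adjusted p = 7.99e-04, and 0.112 with an estimated correlation).

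The remaining cell type lists were not called. Median log2 fold changes were 0.46 for 8 oligodendrocyte markers (camera adjusted p = 0.397), -0.14 for 5 oligodendrocyte precursor markers (0.697), 0.54 for 9 endothelial markers (0.388) and 0.79 for 5 mural and fibroblast markers (0.205). They were 0.035 for 9 markers of glutamatergic pallial neurons (0.122) and 0.66 for 4 of midbrain dopamine neurons (0.249). Of the pallial markers 1 was called, Cux2, which rose from 10.1 ± 3.89 to 46.2 ± 28.9 CPM (SD, n = 4 each; log2 fold change 2.19 ± 0.40 SE, adjusted p = 0.00279). In the other 5 lists edgeR called 0 genes, as did DESeq2 and limma-voom. At an unadjusted p under 0.05 were 2 mural and 1 dopamine neuron markers and 0 of the oligodendrocyte, oligodendrocyte precursor and endothelial markers. The medians of the oligodendrocyte precursor, endothelial and pallial lists changed sign in some fits with 1 library left out. The endothelial list was called toward accumbens without dorsal striatum 3 (adjusted p = 0.0462) or accumbens 2 (0.0430), the mural list without the same libraries (0.0252 and 0.00587). The pallial list was called without dorsal striatum 2 (adjusted p = 0.00912) or accumbens 4 (0.00905). With accumbens 2 and dorsal striatum 3 both left out, the endothelial (adjusted p = 5.69e-04) and mural lists (3.70e-05) were called toward accumbens, and limma-voom called the mural list (0.0497). The myelin gene Mbp stood at 94.2 ± 13.3 CPM in dorsal striatum and 109 ± 65.7 CPM in accumbens, the endothelial gene Flt1 at 15.5 ± 14.5 and 35.9 ± 39.2 CPM and the glutamate transporter gene Slc17a7 at 15.9 ± 18.2 and 41.2 ± 20.6 CPM (SD, n = 4 each). Slc17a7 was called without a filter on low counts (adjusted p = 0.0413). Too few members were abundant enough to test the markers of cholinergic interneurons (0 genes), microglia (1), ependymal cells (1) and choroid plexus (2).

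Neuropeptide precursor genes were shifted toward accumbens, with a median log2 fold change of 0.96 over 12 genes, 4 of them called higher and 0 lower, or 5 and 0 adjusted over the list alone (camera adjusted p = 9.06e-09, and 0.112 with an estimated correlation). Cartpt, whose product is a peptide of feeding and reward circuits, rose from 7.05 ± 2.34 to 40.97 ± 10.5 CPM and Scg2, a granin of secretory vesicles, from 489 ± 84.7 to 847 ± 66.01 CPM (SD, n = 4 each). Penk and Pdyn were the other called members. Of 51 neuromodulator receptor genes, 6 were higher in accumbens and 1, Cnr1, in dorsal striatum, or 10 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0560) except without dorsal striatum 2 (adjusted p = 0.0457), accumbens 3 (0.0468) or accumbens 4 (0.0143). Orphan and adhesion receptors went both ways (2 higher and 4 lower in accumbens of 54, or 5 and 5 adjusted over the list alone, camera adjusted p = 0.882).

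Of 36 sodium and calcium channel genes, 3 were lower in accumbens and 1 higher, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.00893, and 0.211 with an estimated correlation). That call was lost without accumbens 4 (adjusted p = 0.0605). Scn8a, a sodium channel of the axon initial segment, stood at 755 ± 72.8 CPM in dorsal striatum and 443 ± 37.1 CPM in accumbens (SD, n = 4 each). Among 63 potassium channel genes, 6 were lower and 2 higher in accumbens, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.220). A pair of A-type channel genes moved apart, Kcnd2 at -0.87 ± 0.13 SE and Kcnd3 at 1.14 ± 0.17 SE on the log2 scale. Neither 24 glutamate receptor genes (camera adjusted p = 0.445) nor 17 GABA and glycine receptor genes (camera adjusted p = 0.139) were called as lists, the latter being called with the glial marker covariate (adjusted p = 0.0384). In accumbens, 1 glutamate receptor gene was higher and 1 lower, or 4 and 2 adjusted over the list alone, and 2 and 1 of the GABA and glycine receptor genes, or 4 and 1 adjusted over the list alone. The GABA receptor subunit gene Gabrg1 was higher in accumbens (1.60 ± 0.34 SE).

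Among 26 semaphorins, plexins and neuropilins, 7 were higher and 2 lower in accumbens, or 9 and 4 adjusted over the list alone (camera adjusted p = 4.69e-05, and 0.0718 with an estimated correlation). The semaphorin receptor genes Plxna1, Plxna4 and Plxnc1 had log2 fold changes of 1.80 ± 0.34, 1.05 ± 0.17 and 1.13 ± 0.18 SE. Among 17 slit and netrin pathway genes, 4 were higher and 1 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0104, and 0.216 with an estimated correlation), and the call was lost without dorsal striatum 3 (adjusted p = 0.0504) and with fry (0.0557). Ntn1 rose from 6.22 ± 2.86 to 41.6 ± 8.95 CPM and its receptor gene Unc5d from 8.59 ± 2.76 to 28.8 ± 14.4 CPM, the latter not called without accumbens 3 (adjusted p = 0.0577) (SD, n = 4 each). The slit receptor gene Robo2 fell from 170.3 ± 30.4 to 75.7 ± 20.6 CPM. Cadherins and protocadherins (3 higher and 3 lower in accumbens of 76, or 4 and 4 adjusted over the list alone, camera adjusted p = 0.622) were not called as a list, with Pcdh19 at 1.12 ± 0.24 SE and Cdh13 at -1.05 ± 0.22 SE. Among 15 ephrins and Eph receptors, edgeR called 0 of them, 5 at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0 (camera adjusted p = 0.882). Of 55 forebrain patterning transcription factors, 4 were higher and 9 lower in accumbens, or 7 and 12 adjusted over the list alone (camera adjusted p = 0.226). Besides Foxp1, Bcl11b, Ebf1 and Id4, the chromatin organizer gene Satb1 was lower (-1.38 ± 0.31 SE), a call lost without dorsal striatum 4 (adjusted p = 0.0562) and with the glial marker covariate, where the log2 fold change was -1.30 (adjusted p = 0.0908).

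Of 17 RGS genes, 3 were lower and 1 higher, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.00358, and 0.0858 with an estimated correlation), Rgs4 and Rgs9 among them. Of 21 calcium-binding protein genes, 4 were lower and 1 higher, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.0322, and 0.232 with an estimated correlation). That call was lost without dorsal striatum 1 or accumbens 1, 2 or 4, at adjusted p up to 0.0664, and with limma-voom (adjusted p = 0.0603) and fry (0.0582). Calm2, a calmodulin gene, stood at 8097 ± 1238 CPM in dorsal striatum and 4805 ± 531 CPM in accumbens and hippocalcin, Hpca, at 2481 ± 392 and 1340.1 ± 154 CPM (SD, n = 4 each). The activity-induced transcription factor genes Egr1 (1480 ± 175 and 852 ± 118 CPM) and Egr3 (885 ± 120.3 and 516 ± 86.2 CPM) and the synaptic scaffold gene Homer1 (-0.72 ± 0.12 SE) were the 3 called of 23 immediate early genes, whose list was not called (camera adjusted p = 0.0681). The same number of members, 3, was called when adjusted over the list alone, and the list was called lower without a filter on low counts (adjusted p = 0.0404), with the glial marker covariate (0.00413) and with GC and length trends removed (0.0392). It was also called without dorsal striatum 2 (adjusted p = 0.0457), 3 (0.0224) or 4 (0.0317) or accumbens 1 (0.00186). Cyclic nucleotide genes went both ways (2 higher and 4 lower in accumbens of 43, or 7 and 8 adjusted over the list alone, camera adjusted p = 0.700), with the phosphodiesterase gene Pde1a at 1.24 ± 0.13 SE and the phosphatase regulator gene Arpp19 at -0.92 ± 0.14 SE.

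Retinoid and thyroid hormone genes had 4 members higher and 1 lower in accumbens of 20, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0408, and 0.127 with an estimated correlation). Crym, which encodes a thyroid hormone-binding protein, had a log2 fold change of 1.12 ± 0.18 SE and Stra6, which encodes a membrane receptor of vitamin A transport, 2.37 ± 0.39. The list's call was lost without dorsal striatum 2 or 4 or accumbens 1 or 2, at adjusted p up to 0.0638. It was also lost with limma-voom (adjusted p = 0.0718), with GC and length trends removed (0.0718) and with the glial marker covariate (0.0796), with which the median was -0.0069. WNT pathway genes had a median of -0.29 over 26 genes, 2 called lower and 0 higher in accumbens, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0460, and 0.153 with an estimated correlation). That call was lost without dorsal striatum 1, 2 or 3 or accumbens 2, at adjusted p up to 0.224, and over the fits with 1 library left out the median ran from -0.35 to 0.031. It was also lost with limma-voom (adjusted p = 0.118), with thinned libraries (0.0538) and without a filter on low counts (0.350), with which the median was 0.067.

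Cytosolic ribosomal protein genes had a median log2 fold change of 0.24, with 65 of 77 positive (camera adjusted p = 4.69e-05, and 0.529 with an estimated correlation and 0.161 with fry). Among them, edgeR called 0, 11 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Rpl4 stood at 259.8 ± 16.5 CPM in dorsal striatum and 289.6 ± 32.1 CPM in accumbens (SD, n = 4 each). The 80 nuclear-encoded oxidative phosphorylation genes had a median of -0.028 (camera adjusted p = 0.388, and 0.0224 toward dorsal striatum without dorsal striatum 3), and edgeR called 0 of them, 2 at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0, with Atp5b at 1669.7 ± 157 and 1741 ± 37.2 CPM. Medians were 0.081 for 8 interferon and MHC class I genes (camera adjusted p = 0.343) and 0.017 for 18 unfolded protein response and heat shock genes (0.937), among them Hspa8 at 993 ± 86.2 and 1007 ± 42.4 CPM. EdgeR called 0 genes of either list, 2 and 1 at an unadjusted p under 0.05, DESeq2 1 and 0, and limma-voom 1 and 0. The interferon list was called with accumbens 2 and dorsal striatum 3 both left out (adjusted p = 0.0144). The medians of the last 3 lists changed sign when dorsal striatum 1 was left out. The 4 tested sex-linked transcripts were not called (camera adjusted p = 0.998), with the Y-linked gene Ddx3y at 37.7 ± 6.53 and 34.7 ± 9.59 CPM.

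**Figure D3:**
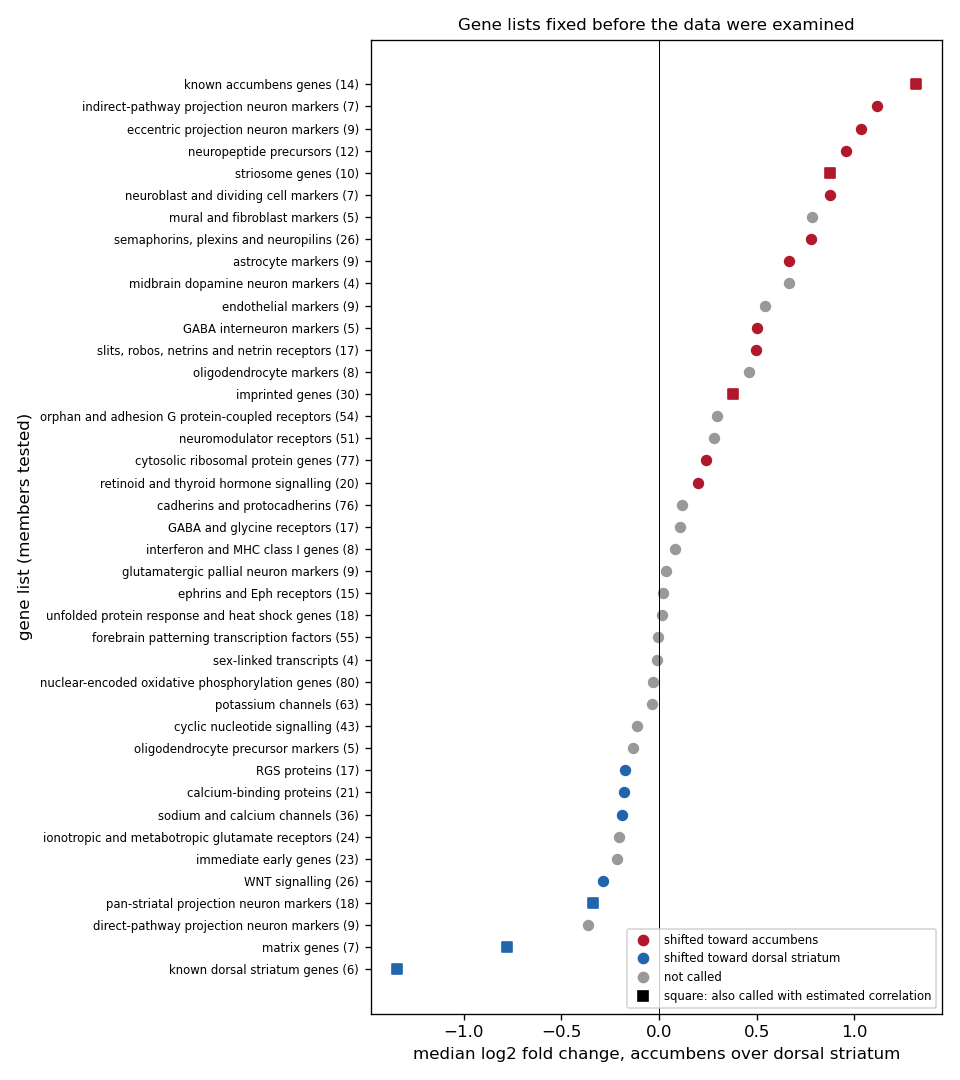
Each mark is the median log2 fold change, accumbens over dorsal striatum, of the tested members of a gene list, with the number of members in parentheses. Red and blue marks are the 13 and 7 lists called by camera with a preset correlation, and squares the 6 that stayed called with an estimated correlation.

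Of 41 lists with enough tested members, 13 were shifted toward accumbens and 7 toward dorsal striatum with camera's preset correlation, at a Benjamini-Hochberg adjusted p under 0.05. With an estimated correlation, 3 and 3 were. They were the known accumbens, striosome and imprinted genes, and the known dorsal striatum, matrix and pan-striatal projection neuron genes. Some of these lists share members, as given above. Other splits of the 8 libraries into 4 and 4 gave up to 14 lists in 1 direction with the preset correlation, and 0 with an estimated correlation. All of these mixed both regions within groups, so they do not show what chance alone would give.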

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

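The tests of indirect-pathway markers against other cell types, and of a uniform dilution of projection-neuron RNA, were chosen after the results were seen, as were the settings that thinned the libraries or removed GC and length trends, and the splits with an estimated correlation.

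The 220 sets of 4 values compared were each of a gene or library measure in 1 region. In 12 of them, 1 library lay far from the other 3. For independent and unselected values, chance gives about 1 in 20, or 11. These sets share libraries and most of their genes were chosen from these data, so 11 is only a rough guide. Dorsal striatum 3 was low for 4 genes that were higher in accumbens. It had 0 CPM of Trhr, where the other dorsal libraries had 2.17 to 3.29, and 16.6 CPM of Nnat against 37.4 to 44.1. Its Cartpt level was 3.60 CPM against 7.88 to 8.80, and its Adora2a level 4.70 CPM against 8.57 to 9.65. Accumbens 1 stood high for Penk (779 CPM against 543 to 552), Egr3 (644 against 465 to 486) and Gpr139 (2.24 against 0.158 to 0.171). Accumbens 2 stood high for Lypd1 (73.7 CPM against 51.1 to 54.01) and Robo2 (106 against 63.2 to 68.1). Accumbens 3 stood high for Rasgrp2 (37.7 CPM against 25.1 to 26.6) and low for Hspa8 (944 against 1027 to 1029.9), and accumbens 4 low for Wfs1 (1188 CPM against 1526 to 1586).

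All 7 tested indirect-pathway markers had positive log2 fold changes, with a median log2 fold change of 1.11, although the tag marks D1 receptor-expressing cells. More RNA of indirect-pathway neurons in the accumbens samples may account for this, and stays open. The 4 markers outside Penk, Drd2 and Adora2a, which were not called, had a median of 0.93. All 7 were already seen to be positive, so that median could not go against this explanation and does not support it. A wider carry-over of RNA from all other cells stays open too: the 42 glial, vascular and interneuron markers had a median of 0.59, 35 of them positive, and the difference between both medians was not past the threshold (two-sided permutation p over genes = 0.172, 100000 resamples). The most abundant of these marker genes by CPM, Penk, reached 606 ± 115 CPM in accumbens, Slc1a2 433 ± 173 CPM and Mbp 109 ± 65.7 CPM (SD, n = 4 each), against 435 ± 86.5 CPM for Drd1. CPM is not corrected for transcript length, so these values do not compare transcript numbers between genes. Penk, Drd2 and Adora2a are also on the neuropeptide and receptor lists. The indirect-pathway list stayed called with the glial marker covariate (median 0.88, camera adjusted p = 2.44e-05 with the preset correlation), as did Penk (log2 fold change 1.17, adjusted p = 0.00209). Drd2 (0.88, adjusted p = 0.183) and Adora2a (1.16, adjusted p = 0.266) were not called with it. Even without the covariate, the list was not called with an estimated correlation (camera adjusted p = 0.0917). The covariate stands for glial RNA through 18 markers, so these values do not settle whether such RNA is the whole cause. Other cells and, untested, a regional difference in how many tagged cells express both sets of genes also stay open.

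Of 222 called genes of at least 100 CPM, 163 were lower in accumbens, or 73.4%, against 40% of 70 called genes under 20 CPM, while over all 2124 tested genes of at least 100 CPM the median log2 fold change was -0.061, and 0.085 under 20 CPM. The larger accumbens libraries are unlikely to account for it, since the share was 72.6% after thinning all libraries to equal totals, and neither are GC content and transcript length, since it was 74.4% after removing their trends. A uniform dilution of projection-neuron RNA, by RNA that held none of the 18 pan-striatal markers, would move them by 1 amount. They spread from -1.26 to 0.28 on the log2 scale, with a homogeneity statistic of 10.6 per degree of freedom (chi-square p = 2.88e-29). That p takes the genes as independent, although they were measured in the same libraries. The spread argues against such a dilution as the whole cause. A dilution by RNA that held some of these markers stays open. So does a partial dilution or a regional difference in expression itself, and none of these was tested.

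The counts were compared with those of all 35 splits of the 8 libraries into 4 and 4. As many genes higher in accumbens (200), higher in dorsal striatum (264) or changed at least 2-fold (240) came only from the real split. That is 1 of 35, the smallest share possible, and the highest other split gave 0 in each case. Every other split put libraries of both regions in each group, so a regional difference would widen its within-group spread and lower its counts. The comparison therefore cannot exclude chance. For the counts of lists with a preset correlation, the larger of a split's 2 directions was compared with each real count. Of the 35 splits, the real split included, 4 gave at least 13 lists and 12 gave at least 7, and the highest other split gave 14. Most of those other splits had groups mainly from a single region and so kept part of the regional difference. They neither exclude chance nor show that chance alone gives such counts. With an estimated correlation, only the real split, 1 of 35, gave the 3 lists in each direction, and the highest other split gave 0. The mixed regions of the other splits limit this comparison in the same way, so it cannot exclude chance either.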

How the results depend on the processing

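The tests that thinned the libraries, left out Rn45s, Lars2 and AK140265, removed GC and length trends, or left out accumbens 2 and dorsal striatum 3 together were chosen after seeing the data. Of the 200 genes higher in accumbens, 264 higher in dorsal striatum and 240 changed at least 2-fold, DESeq2 gave 375, 388 and 369, and no filter on low counts, with more genes tested, gave 350, 346 and 371. With the glial marker covariate they were 117, 150 and 172, with 253 of its 267 calls among the 464. The cause was not tested for DESeq2, the missing filter or the covariate. Of genes of at least 100 CPM, 278 were called without the filter and 222 with it. Newly tested genes therefore do not account for all of the added calls. Leaving out 1 library gave 139 to 191 genes higher in accumbens, 184 to 236 higher in dorsal striatum, 187 to 248 changed at least 2-fold, 10 to 15 lists toward accumbens and 5 to 9 toward dorsal striatum. Without accumbens 2 and dorsal striatum 3 together, 140 and 190 genes were called, and Col12a1, Lcp2, Oprd1, Fat4, Sfrp1, Adora2a, Slc1a2, Lars2 and the astrocyte, slit and netrin, retinoid and WNT lists lost their calls, while Drd1 and the direct-pathway, endothelial, mural and interferon lists gained one. Camera with an estimated correlation called 3 lists toward accumbens and 3 toward dorsal striatum in place of 13 and 7, and fry 9 and 7, though fry tests a list on its own and not against other genes. The other alternatives kept these counts within 1.5 times. Equal replicate numbers did not mark shared deviations, as the 4 same-number correlations of deviations from region means lay between -0.0811 and 0.0140. The replicate block gave 194 genes higher in accumbens, 238 higher in dorsal striatum, 235 changed at least 2-fold, and 14 and 7 lists. Sfrp1, AK140265 and the WNT list were not called with it, and the glutamatergic pallial (median 0.66, adjusted p = 0.0246) and immediate early gene lists (0.0230) were. Over 201 genes and 4017 gene results, 3787 kept their side of the threshold, 84 of them with another sign and no call either way, 203 lost the call, 27 gained one, and no called gene changed sign. Of the 41 lists' 860 results, 61 lost and 32 gained a call. Leaving out mitochondrially encoded genes gave no value, since no gene symbol matched them. Genes under 5 CPM had a median fitted biological coefficient of variation of 0.773, against 0.171 over 100 CPM, so differences among them are more easily missed.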

Other observations

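The tests of calcium signalling and copine genes were chosen after their values were seen. Genes of calcium and calmodulin signalling were among the most abundant transcripts called lower in accumbens. Of all called genes of at least 100 CPM, 163 of 222 were lower there, so that direction alone does not set these genes apart. Ppp3ca, the catalytic subunit of calcineurin, stood at 4529.5 ± 567 CPM in dorsal striatum and 2290 ± 214 CPM in accumbens (SD, n = 4 each), and its regulatory subunit gene Ppp3r1 at 1885 ± 301 and 1105 ± 121 CPM. The calmodulin-dependent kinase gene Camk4 had a log2 fold change of -1.06 ± 0.12 SE, the plasma membrane calcium pump gene Atp2b1 -0.99 ± 0.12, the protein kinase C gene Prkcb -0.84 ± 0.14 and the calcium release channel gene Itpr1 -0.65 ± 0.12. In the other direction, the copine genes Cpne6, Cpne2 and Cpne4, which encode calcium-dependent phospholipid-binding proteins, had log2 fold changes of 1.32 ± 0.16, 1.31 ± 0.18 and 1.61 ± 0.34 SE, and Cpne4 lost its call without accumbens 3 (adjusted p = 0.0506).

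Whether these genes stand for wider groups was tested on members that had not been noticed first. The 24 other calcium and calmodulin signalling genes had a median log2 fold change of -0.056 (camera adjusted p over both groups = 0.574). Of these, edgeR called 0, 7 at an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0, which leaves open whether the wider group is lower. The 6 other copines had a median of -0.087 (camera adjusted p over both groups = 0.911) and went both ways, from -1.68 to 1.89. The 3 of them that averaged at least 20 CPM lay between -0.23 and 0.0051, which argues against a difference of the whole family like that of the first 3. Of the 6 others, edgeR called 0, 1 at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0.

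A pair of transcripts with very high counts was also called higher in accumbens. Lars2 stood at 3287 ± 387 and 4563 ± 397 CPM and AK140265 at 1685 ± 676 and 6565 ± 6754 CPM (SD, n = 4 each). Lars2 lost its call without accumbens 2 or accumbens 4 (adjusted p up to 0.0668), and AK140265 without dorsal striatum 1, 3 or 4, at adjusted p up to 0.0771. The log2 fold change of AK140265, 1.96 with all libraries, was 0.93 without accumbens 1 (adjusted p = 0.0410). With the glial marker covariate the log2 fold changes were 0.47 for Lars2 (adjusted p = 0.0745) and 1.07 for AK140265 (0.448), and DESeq2 did not call AK140265 (0.132). Leaving both and Rn45s out of the library sizes gave 198 genes higher in accumbens and 264 higher in dorsal striatum. Rn45s itself took 3.58% of gene counts in dorsal striatum and 6.11% in accumbens (two-sided exact permutation p = 0.0571). The cause of the differences in Lars2 and AK140265 was not tested.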
